A study of Mus musculus with 12 samples.

How the data were processed

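RNA was sequenced from 12 mouse PGCLC cultures, 3 biological replicates in each of 4 groups. Per the labels, total RNA was extracted with Trizol, treated with DNase and cleaned on RNeasy columns, and libraries were made from at least 10 ng with the SMARTer Stranded Total RNA-Seq Pico Input kit. Such libraries are not limited to RNA with a poly(A) tail, so that histone mRNAs without one are counted as well. Transcripts annotated as ribosomal RNA took 0.91 to 2.15% of the counts in matched genes.

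The deposited values are estimated counts per transcript (kallisto expected counts), not scaled to depth, beside transcript lengths and effective lengths in bases. The authors also give TPM, scaled by kallisto to effective length and depth, which were not used here. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.2 and quantified with kallisto on GRCm38 (mm10). The version of kallisto and the transcript set are not given in the sources used here. Other days of the differentiation that the series description mentions are not analysed here.

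Each library lists 119414 transcripts, of which 116728 (97.8%) were matched by Ensembl transcript ID, without the version, to GENCODE M21, and 2686 were not. Estimated counts were summed per gene and rounded, for 35975 genes, 21897 of them protein coding and 13518 pseudogenes. Matched genes held 6286329 to 8820668 counts per library, and unmatched transcripts 2.68 to 4.32% of the counts. Mitochondrially encoded mRNAs took 1.08 to 1.87% of the counts, pseudogenes 6.82 to 9.6%, and Lars2 with Ccnb1ip1, which hold reads like ribosomal RNA, 1.3 to 3.06%. PCR copies carry no molecular identifiers here, so floors cover counting error only.

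Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 16178 genes, 15113 protein coding and 1032 pseudogenes. edgeR 4.0.16 was used with TMM normalisation (factors 0.927 to 1.063) and a quasi-likelihood fit of all 12 libraries with 1 mean per group. The biological coefficient of variation was 0.241. The F-tests are two-sided, and a gene is called at a Benjamini-Hochberg adjusted p below 0.05, with no minimum fold change. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of F. CPM use the TMM library sizes and are given as mean and SD over 3 replicates. A gene with no count in a group is given a lower bound on its fold from a floor of 3 counts over the group. Calculations ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

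Comparisons were TKO_40h with WT_40h, TKO_48h and TKO_96h with TKO_40h, TKO_96h with TKO_48h, TKO_48h and TKO_96h with WT_40h, and the 3 priming times of TKO together. Before the data were examined, 27 gene lists (613 genes, 605 of them among the genes in the files, 22 in more than 1 list) were fixed from general knowledge, with markers of 6 other kinds of cell. A list needed 5 tested members. Lists were tested with camera (limma 3.58.1, two-sided, preset inter-gene correlation 0.01), with camera under an estimated correlation, and with fry, each adjusted over the 27 lists of a comparison. Fry asks whether the members of a list move, on balance, in 1 direction and does not compare them with other genes.

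The genes named were set by a rule fixed beforehand. For each of the 3 main comparisons it takes the 8 largest increases and the 8 largest decreases among called genes with at least 5 CPM in the higher group, replicates that do not overlap and a symbol that is not a predicted gene. It adds up to 4 called members of each list from the smallest adjusted p on, or the 2 members of highest CPM for a list with none, and Dnmt1, Dnmt3a and Dnmt3b always. Genes outside the rule are marked as chosen after their values were seen.

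Replicate numbers were not used as a pairing: correlations between the deviations of same-numbered libraries from their group means ran from -0.06 to 0.051 over 18 pairs. The procedure was tested on simulated counts, drawn independently for each gene from its mean over all libraries and its fitted dispersion. Only genes with a mean of at least 5 CPM were changed. Correlation between genes, other differences between groups and libraries that stand apart were not simulated. In these counts the procedure recovered 64 to 69% of genes changed 2-fold and 95 to 98% of those changed 4-fold, with 3 to 6.2% of calls false. Alternatives tried were RLE size factors, DESeq2 1.42.0, no filter on low counts, a replicate block, an effective length offset, a robust fit, only the groups compared, each library left out in turn and, chosen after seeing the data, protein-coding genes alone without Lars2, Ccnb1ip1 and Gm20594, the methylation list without the 3 targeted genes and the gene families without TKO_96h replicate 1.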

Results

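The series holds 12 RNA sequencing libraries from cultures of mouse primordial germ cell-like cells (PGCLCs), cells that resemble the first germ cells of the embryo and are made in culture from embryonic stem cells. The starting line was E14TG2a, a mouse embryonic stem cell line kept in 2i medium with vitamin C, as wild type (WT) or as a line labelled TKO, known from the study to carry knockouts of Dnmt1, Dnmt3a and Dnmt3b. Stem cells were first primed to epiblast-like cells (EpiLCs) for 40, 48 or 96 h and then induced as aggregates for 4 days with BMP4, BMP8, SCF, EGF and LIF. The 4 groups of 3 biological replicates were WT primed for 40 h (WT_40h) and TKO primed for 40, 48 or 96 h (TKO_40h, TKO_48h, TKO_96h), so that WT was sequenced at 1 priming time. The labels describe dissociation for flow cytometry but do not say whether RNA came from sorted cells or from whole aggregates.

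Each library held between 6570180 and 9114128 estimated counts, 7389986 to 9114128 in WT_40h, 7535501 to 8798136 in TKO_40h, 6570180 to 7362584 in TKO_48h and 7090449 to 7828031 in TKO_96h. Between 13562 and 15459 genes reached 10 counts in a library. Correlations of log2 CPM (counts scaled to a common library size) between replicates, across genes, which are not independent replicates, lay between 0.95 and 0.957 in WT_40h, TKO_40h and TKO_96h and between 0.931 and 0.945 in TKO_48h. The first principal component, with 21.9% of the variance, placed the 3 TKO_96h libraries between 56.7 and 70.1 and all others between -43.7 and -7.9. TKO_48h replicate 1 stood apart on the second component (-85.6, with -20.7 the next lowest), took 14.57% of its counts from its top 10 genes and had the lowest number of genes with 10 counts, 13562. TKO_96h replicate 1 stood apart within its group, with 3.06% of its counts from Lars2 and Ccnb1ip1 against 1.64 and 1.48% in replicates 2 and 3. Transcripts annotated as ribosomal RNA took 1.78 to 2.15% of the counts in TKO_48h, 0.91 to 1.11% in TKO_40h, 0.93 to 1.29% in WT_40h and 1.24 to 1.63% in TKO_96h.

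The 3 targeted DNA methyltransferase genes were lower in TKO_40h than in WT_40h, yet transcripts of each were still counted. Dnmt1, which copies methylation at replication (GRCm38 chromosome 9, 20907209 to 20959888), was at 120 ± 8.63 CPM in TKO_40h and 439 ± 12 CPM in WT_40h (mean ± SD, n = 3), a log2 fold change of -1.87 ± 0.16 (SE, adjusted p = 9.9e-07). Dnmt3a, a de novo methyltransferase (chromosome 12, 3806007 to 3914443), was at 64.3 ± 3.97 against 406 ± 41.5 CPM, a log2 fold change of -2.66 ± 0.17 (adjusted p = 3e-08). Dnmt3b, the other de novo enzyme (chromosome 2, 153649450 to 153687730), was at 47.9 ± 8.28 against 185 ± 28.9 CPM, a log2 fold change of -1.95 ± 0.17 (adjusted p = 9.9e-07). In TKO_48h and TKO_96h, Dnmt1 was at 86.9 ± 30.2 and 144 ± 10.6 CPM, Dnmt3a at 35 ± 12.1 and 63.7 ± 8.25 CPM, and Dnmt3b at 18.3 ± 4.38 and 32.3 ± 4.1 CPM, each below WT_40h with an adjusted p of at most 7.7e-07. Dnmt3l, the catalytically inactive partner of the de novo enzymes, went the other way: 452 ± 12.4 CPM in TKO_40h against 140 ± 11.8 CPM in WT_40h, a log2 fold change of 1.69 ± 0.12 (adjusted p = 6.2e-08). Counts per gene do not show whether a transcript carries the deletion or frameshift of a knockout allele.

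**Figure D1:**
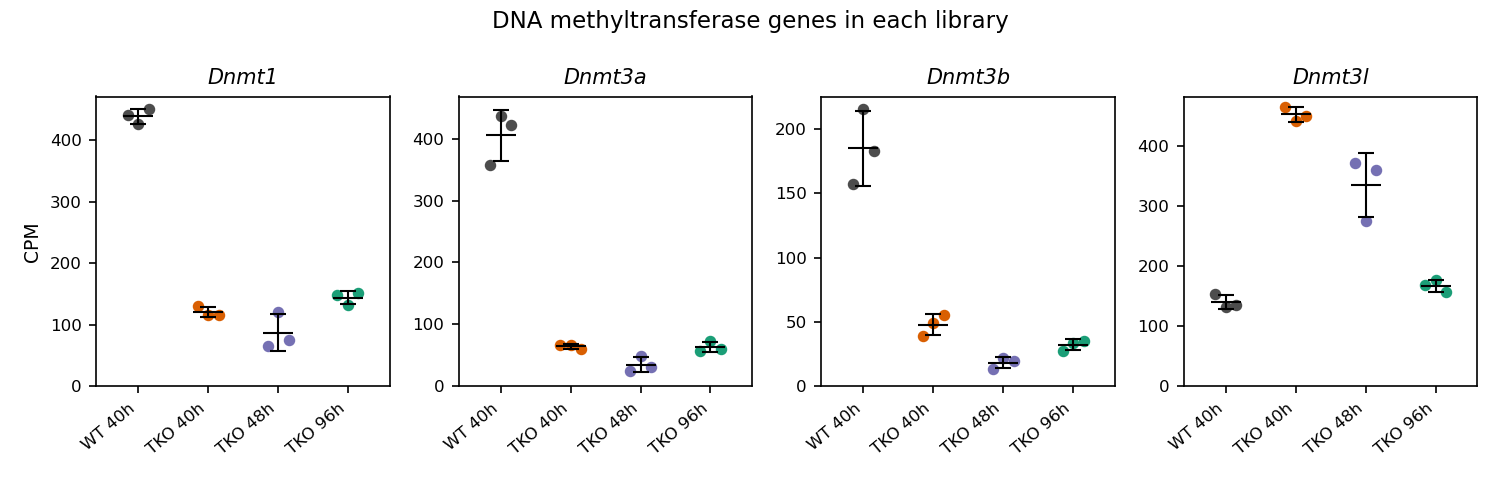
CPM (vertical axis, linear from 0) of Dnmt1, Dnmt3a, Dnmt3b and Dnmt3l in each library (points), by group (horizontal axis), with the mean and SD of the 3 replicates as bars. Dnmt1, Dnmt3a and Dnmt3b are lower in every TKO group than in WT_40h, while the mean of Dnmt3l is 140 CPM in WT_40h, 452 in TKO_40h, 335 in TKO_48h and 168 in TKO_96h.

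The comparison of TKO_40h with WT_40h asks which genes differ between the genotypes at the same priming time. The sample titles name E14 WT and E14 TKO cells and no separate clones. Other differences between the WT and TKO lines therefore cannot be told apart from the effect of the knockouts. Next to the methyltransferase genes, the placental and imprinted gene Peg10 (chromosome 6, 4747306 to 4760517) was higher in TKO_40h, at 3120 ± 69.3 against 1230 ± 114 CPM (log2 fold change 1.34 ± 0.12, adjusted p = 2.2e-06). The imprinted growth regulators Grb10 and Cdkn1c were also higher, by log2 fold changes of 2.08 ± 0.18 and 2.29 ± 0.27 (adjusted p = 9.9e-07 and 8.7e-05). Among germ cell genes, Dppa3, a maternal and germline factor, was at 51.5 ± 5.44 against 16.7 ± 3.81 CPM (1.63 ± 0.2, adjusted p = 0.00015), and the germline genes Tex19.1 and Dazl were higher by 0.89 ± 0.12 and 0.73 ± 0.14 (adjusted p = 0.00034 and 0.0068). The germ cell receptor gene Kit and the germline genes Meioc and Sohlh2 were lower by -0.78 ± 0.15, -0.76 ± 0.19 and -0.58 ± 0.16 (adjusted p = 0.0065, 0.037 and 0.046).

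In all, 501 of 16178 genes differed between TKO_40h and WT_40h, 262 higher and 239 lower in TKO_40h, and 168 of them at least 2-fold (99 higher, 69 lower). Rankings of the largest changes keep to the limits of the naming rule: at least 5 CPM in the higher group, no overlap of replicates and no predicted genes. Within them, the largest increases were those of Sox18, an endothelial transcription factor, Muc19, Gpat3, Anxa1, Dcdc2a, H2-Bl, Smyd1 and Hand1, a mesoderm and placenta factor, with log2 fold changes from 3.68 to 2.35. Within the same limits, the largest decreases, next to Dnmt3a and Dnmt3b, were those of Bcl11b, Dnah10, Ccdc113, Tmem132d, Prmt8 and Calhm2, from -2.38 to -1.99. Apart from the methyltransferase genes, Prmt8 and Muc19, these genes lay at or under 11.9 CPM in both groups. Tmem72 (chromosome 6, 116679063 to 116716913), at 3260 ± 262 against 1220 ± 345 CPM, was singled out after its values were seen and was higher by 1.42 ± 0.22 (adjusted p = 0.0013). In its longest GENCODE M21 transcript 33% of the 31-base words also occur in another gene of GENCODE M21. Whether all these transcripts are among those listed for the libraries was not checked. The counts of Tmem72 are thus uncertain to an unknown degree, and its call ended with a robust quasi-likelihood fit (adjusted p = 0.051).

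Of 27 gene lists, fixed before the data were examined, 13 were called between TKO_40h and WT_40h by camera with a preset correlation, and 1, the p53 targets, also with an estimated correlation. Among the p53 targets, 0 of 23 tested members were higher and 5 lower (0 and 10 adjusted over the list alone), with the kinase gene Plk2 lower by a log2 fold change of -0.78 ± 0.15. The p53 list gave adjusted p = 7.8e-07, and adjusted p = 0.024 with an estimated correlation. Hypoxia and glycolysis genes were lower (0 of 23 higher and 2 lower, 0 and 4 adjusted over the list alone), led by the oxygen sensor Egln1 at 74.2 ± 1.21 against 134 ± 9.13 CPM. The hypoxia list gave adjusted p = 7.8e-07, and adjusted p = 0.098 with an estimated correlation. BMP targets were lower (0 of 13 higher and 4 lower, 0 and 4 adjusted over the list alone), led by the signalling inhibitor Smad7 at -0.58 ± 0.11. The BMP list gave adjusted p = 0.015, and adjusted p = 0.18 with an estimated correlation. Cholesterol biosynthesis genes were lower as a list (adjusted p = 0.016, adjusted p = 0.46 with an estimated correlation) with 0 of 20 members called and 0 higher and 1 lower adjusted over the list alone. For the DNA methylation machinery the test pointed down (1 of 18 higher and 3 lower, 3 and 3 adjusted over the list alone) with a mean of -0.24 and a median of 0.05. The methylation list gave adjusted p = 0.015, and adjusted p = 0.098 with an estimated correlation. Its 3 lower members are the genes targeted in TKO, so the genotype set this result. Without them, a test chosen after the values were seen, the DNA methylation machinery had 1 of 15 higher and 0 lower (3 and 0 adjusted over the list alone) and the test pointed up (adjusted p = 0.017, adjusted p = 0.11 with an estimated correlation).

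Of the 6 lists of other lineages, the trophoblast, endothelium and endoderm lists were called higher in TKO_40h, none of them with an estimated correlation. Trophoblast genes had a median log2 fold change of 0.82 with 1 of 12 higher, Peg10, and 0 lower (1 and 0 adjusted over the list alone). The trophoblast list gave adjusted p = 1.4e-05, and adjusted p = 0.07 with an estimated correlation. Endothelium and blood genes had 2 of 14 higher and 0 lower (2 and 0 adjusted over the list alone). The endothelium list gave adjusted p = 0.0077, and adjusted p = 0.19 with an estimated correlation. Endoderm genes had 1 of 19 higher and 0 lower (2 and 0 adjusted over the list alone). The endoderm list gave adjusted p = 0.012, and adjusted p = 0.19 with an estimated correlation. The 2-cell-like genes, such as the Zscan4 and Usp17l copies, which share most of their sequence so that counts per copy are uncertain, had a median of 1.26 with 0 of 15 called (5 higher and 0 lower adjusted over the list alone). The 2-cell-like list gave adjusted p = 2.9e-05, and adjusted p = 0.12 with an estimated correlation. Summed over 8 Zscan4 copies, the level was 134 ± 20.6 CPM in TKO_40h and 69.1 ± 35 CPM in WT_40h.

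Immediate early genes were higher in TKO_40h (1 of 19 higher and 0 lower, 6 and 0 adjusted over the list alone), with the growth factor response gene Egr1 at 251 ± 35 against 141 ± 7.4 CPM. The immediate early list gave adjusted p = 0.00028, and adjusted p = 0.12 with an estimated correlation. Cell cycle genes were higher with a median of 0.14 (2 of 26 higher and 0 lower, 7 and 0 adjusted over the list alone). The cell cycle list gave adjusted p = 0.00059, and adjusted p = 0.29 with an estimated correlation. Paternally expressed imprinted genes with a maternally methylated control region had 3 of 21 higher, led by Peg10, and 0 lower (3 and 0 adjusted over the list alone), with a mean of 0.14 and a median of -0.06. The paternally expressed list gave adjusted p = 0.042, and adjusted p = 0.12 with an estimated correlation. The other imprinted genes had 2 of 16 higher, Grb10 and Cdkn1c, and 1 lower (2 and 1 adjusted over the list alone). The other imprinted list gave adjusted p = 0.011, and adjusted p = 0.098 with an estimated correlation.

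The remaining 14 lists were not called between TKO_40h and WT_40h, among them PGC specification (2 of 20 higher and 2 lower, 5 and 2 adjusted over the list alone; adjusted p = 0.48) and methylation-sensitive germline genes (2 of 37 higher and 2 lower, 4 and 3 adjusted over the list alone; adjusted p = 0.35). Naive pluripotency genes had 3 of 20 higher and 1 lower (adjusted p = 0.31), formative and primed genes 2 of 22 higher and 2 lower (adjusted p = 0.25), and interferon-stimulated genes 3 of 24 higher and 1 lower (adjusted p = 0.15). The lower formative genes include Dnmt3b, a gene targeted in TKO. The X-linked Rhox and Xlr genes (adjusted p = 0.33), mesoderm (0.13), neural (0.5), surface ectoderm (0.13), integrated stress response (0.17), WNT target (0.56), Hox (0.56), mitochondrially encoded (0.088) and cytosolic ribosomal protein lists (0.063) each had at most 2 members called. Median, mean and test differed in sign for the PGC, germline and formative lists, whose medians were -0.04, -0.03 and -0.09 and whose means were 0.01, 0.03 and 0.04.

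Without single libraries the number of genes called between TKO_40h and WT_40h fell to 217, 181 and 208 (WT_40h replicates 1, 2 and 3) and to 189, 208 and 205 (TKO_40h replicates 1, 2 and 3). The call of Prmt8 ended without TKO_40h replicate 1 (adjusted p = 0.052), that of Bcl11b without TKO_40h replicate 1 or 2 (at most 0.075), and that of Sox18 without WT_40h replicate 1 or 3 or TKO_40h replicate 3 (at most 0.069). That of Gpat3 ended without WT_40h replicate 1 or 3 or TKO_40h replicate 2 or 3 (at most 0.19), and that of Dnah10 without WT_40h replicate 1 or 2 or TKO_40h replicate 1 or 3 (at most 0.099). The call of Smyd1 ended without any 1 library but TKO_40h replicate 3 (at most 0.11), that of Ccdc113 without any but TKO_40h replicate 1 (at most 0.19), and those of H2-Bl, Tmem132d and Calhm2 without any of the 6 (at most 0.12, 0.15 and 0.15). Among the lists, endoderm and cholesterol biosynthesis were not called without WT_40h replicate 1 (adjusted p = 0.069 and 0.055), BMP targets without TKO_40h replicate 3 (0.096), and the paternally expressed imprinted genes without WT_40h replicate 1, TKO_40h replicate 2 or TKO_40h replicate 3 (0.11, 0.065 and 0.05). With an offset for effective transcript length 77 genes were called, with Dnmt1, Dnmt3a, Dnmt3b, Dnmt3l, Peg10, Grb10, Cdkn1c, Dppa3, Egln1, Egr1, Muc19, Dcdc2a and Tmem72 among them; the calls of Anxa1, Hand1, Tex19.1, Dazl, Plk2 and Smad7 ended (adjusted p = 0.24, 0.14, 0.053, 0.13, 0.15 and 0.18). The calls of the 10 genes that depended on single libraries ended as well, with adjusted p values from 0.066 for Sox18 and Prmt8 to 0.83 for Dnah10. The call of Kit ended without WT_40h replicate 1 (adjusted p = 0.054) and held with the offset. That of Sohlh2 ended without any 1 library but TKO_40h replicate 2 (at most 0.24) and that of Meioc without any of the 6 (at most 0.18), and with the offset both ended (adjusted p = 0.19 and 0.68). Without a filter on low counts 787 genes were called, and 1279 in a fit on the 6 libraries alone.

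The comparison of TKO_48h with TKO_40h asks what 8 more hours of priming change within TKO. Genes of hypoxia and glycolysis were higher in TKO_48h and immediate early genes lower. Egln1 was at 175 ± 10.2 against 74.2 ± 1.21 CPM (log2 fold change 1.24 ± 0.11, adjusted p = 3.1e-06) and the glycolytic enzyme gene Aldoa at 1740 ± 231 against 1110 ± 35.3 CPM (0.64 ± 0.1, adjusted p = 0.00079). Ero1l, an oxidase of protein folding, and Ndrg1, a stress-response gene, both known to be induced by hypoxia, were higher by 0.99 ± 0.13 and 1.24 ± 0.18 (adjusted p = 0.00025 and 0.00036). The early growth response gene Egr1 (chromosome 18, 34859823 to 34864984) was at 38.4 ± 8.9 against 251 ± 35 CPM (-2.71 ± 0.16, adjusted p = 4e-09), and the AP-1 genes Fosb and Fos were lower by -3.7 ± 0.26 and -2.14 ± 0.27 (adjusted p = 7.8e-08 and 0.00017). The targeted genes Dnmt3a and Dnmt3b were lower by -0.87 ± 0.17 and -1.38 ± 0.18 (adjusted p = 0.006 and 0.00018), while Dnmt1, at -0.47 ± 0.16, did not pass (adjusted p = 0.1). Dnmt1 did pass without a filter on low counts (adjusted p = 0.0055), with DESeq2 (adjusted p = 0.049) and without TKO_48h replicate 2 (adjusted p = 0.00028).

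Between TKO_48h and TKO_40h, 888 of 16178 genes were called, 415 higher and 473 lower in TKO_48h, and 244 of them at least 2-fold (124 higher, 120 lower). Within the limits of the naming rule, the largest increases were those of Hcn4, Car9, a hypoxia-induced carbonic anhydrase, Bcl11b, Pnmal2, Grin1, Pdgfrb, Selenbp1 and Sec14l5, with log2 fold changes from 3.67 to 2.03. The largest decreases within them, besides Fosb, Egr1 and Fos, were those of Pgbd1, Hdx, Pramel7, Tmem72 and Usp17lc, from -4.37 to -2.15. Tmem72 was at 681 ± 91.4 against 3260 ± 262 CPM (-2.26 ± 0.23, adjusted p = 1.3e-05).

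Of the 27 lists, 12 were called between TKO_48h and TKO_40h, and 3 of these also with an estimated correlation: hypoxia and glycolysis, immediate early genes and the DNA methylation machinery. Hypoxia and glycolysis genes had 18 of 23 higher and 0 lower (19 and 0 adjusted over the list alone), a median log2 fold change of 0.55 and adjusted p values of 5.9e-25 and 0.01 with an estimated correlation. Immediate early and dissociation response genes had 1 of 19 higher and 9 lower (2 and 11 adjusted over the list alone), a median of -0.71 and adjusted p values of 7.2e-14 and 0.011 with an estimated correlation. The DNA methylation machinery had 0 of 18 higher and 4 lower (0 and 6 adjusted over the list alone), with the chromatin remodeller gene Hells at 469 ± 26.3 against 758 ± 17.8 CPM. The methylation list gave adjusted p = 3.5e-05, and adjusted p = 0.011 with an estimated correlation. Without the 3 targeted genes, again chosen after the values were seen, the DNA methylation machinery had 0 of 15 higher and 2 lower (0 and 3 adjusted over the list alone; adjusted p = 0.011, adjusted p = 0.085 with an estimated correlation).

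PGC genes were higher in TKO_48h (3 of 20 higher and 1 lower, 8 and 1 adjusted over the list alone), with the surface markers of early germ cells Ifitm1 and Ifitm3 higher by 1.15 ± 0.22 and 1.17 ± 0.23. The PGC list gave adjusted p = 0.0014, and adjusted p = 0.08 with an estimated correlation. Methylation-sensitive germline genes were lower (0 of 37 higher and 6 lower, 0 and 7 adjusted over the list alone), with Dazl, Tex11 and Tuba3b lower by -0.97 ± 0.14, -0.92 ± 0.16 and -1.2 ± 0.2. The germline list gave adjusted p = 0.00067, and adjusted p = 0.085 with an estimated correlation. Formative and primed pluripotency genes were lower (2 of 22 higher and 6 lower, 2 and 10 adjusted over the list alone). The formative list gave adjusted p = 0.0024, and adjusted p = 0.34 with an estimated correlation. The Nodal antagonist gene Lefty2 was higher by 0.97 ± 0.13 and the primed epiblast marker Fgf5 lower by -1.42 ± 0.26. The 2-cell-like genes were lower (0 of 15 higher and 5 lower, 1 and 8 adjusted over the list alone), and the summed Zscan4 copies were at 35.3 ± 12.7 CPM. The 2-cell-like list gave adjusted p = 2.4e-05, and adjusted p = 0.12 with an estimated correlation. BMP targets were higher (2 of 13 higher and 0 lower, 4 and 1 adjusted over the list alone). The BMP list gave adjusted p = 0.0024, and adjusted p = 0.12 with an estimated correlation. The p53 targets were higher too (3 of 23 higher and 0 lower, 3 and 0 adjusted over the list alone). The p53 list gave adjusted p = 0.0039, and adjusted p = 0.085 with an estimated correlation. In TKO_48h against WT_40h the p53 targets had 0 of 23 higher and 1 lower and were not called (camera with the preset correlation, adjusted p = 0.12).

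Cholesterol biosynthesis genes were higher in TKO_48h (2 of 20 higher and 0 lower, 3 and 0 adjusted over the list alone). The cholesterol list gave adjusted p = 0.00067, and adjusted p = 0.34 with an estimated correlation. Cell cycle genes were lower (0 of 26 higher and 4 lower, 1 and 8 adjusted over the list alone), led by the proliferation marker Mki67 at -0.51 ± 0.11. The cell cycle list gave adjusted p = 0.0028, and adjusted p = 0.4 with an estimated correlation. Mitochondrially encoded mRNAs were lower (0 of 13 higher and 3 lower, 0 and 7 adjusted over the list alone), and took 1.08 to 1.19% of the counts in the same 3 libraries whose share of ribosomal RNA was 1.78 to 2.15%. The mitochondrial list gave adjusted p = 0.0015, and adjusted p = 0.4 with an estimated correlation. The other 15 lists were not called, with adjusted p values between 0.069 for mesoderm, 0 of 20 members called, and 0.91 for interferon-stimulated genes, 0 of 24 called. Median, mean and test differed in sign for the interferon-stimulated, WNT target, paternally expressed imprinted and other imprinted lists.

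Without single libraries the number of genes called between TKO_48h and TKO_40h fell to 324, 400 and 394 (TKO_40h replicates 1, 2 and 3), to 551 without TKO_48h replicate 1, the library that stood apart, and to 492 without TKO_48h replicate 3. Without TKO_48h replicate 2 it rose to 1107. The formative and cell cycle lists were not called without TKO_48h replicate 2 (adjusted p = 0.2 for each). The call of Pgbd1 ended without TKO_40h replicate 1 (adjusted p = 0.051), that of Sec14l5 without TKO_40h replicate 1 or 2 (at most 0.1), that of Pnmal2 without TKO_40h replicate 1 or 3 or TKO_48h replicate 1 (at most 0.1), and that of Pdgfrb without TKO_40h replicate 2 or 3 or TKO_48h replicate 1 (at most 0.085). The calls of Hcn4 and Hdx ended without any 1 library but TKO_48h replicate 1 (at most 0.15 and 0.091), that of Pramel7 without any but TKO_48h replicate 3 (at most 0.13), that of Usp17lc without any but TKO_48h replicate 2 (at most 0.16), and those of Car9 and Selenbp1 without any of the 6 (at most 0.14 and 0.16). With the length offset 203 genes were called; the calls of Dnmt3a (-0.12, adjusted p = 0.89), Bcl11b (0.078), Grin1 (0.18) and Ero1l (0.11) ended, while those of Dnmt3b, Hells, Egln1, Ndrg1, Aldoa, Egr1, Fosb, Fos, Fgf5, Lefty2, Dazl, Tex11, Tuba3b, Ifitm1, Ifitm3, Mki67, Pgbd1, Sec14l5 and Tmem72 held. The calls of Hcn4, Car9, Pnmal2, Pdgfrb, Selenbp1, Hdx, Pramel7 and Usp17lc ended too, with adjusted p values from 0.063 for Pnmal2 and Pdgfrb to 0.23 for Pramel7. In a fit on the 6 libraries alone those of Car9, Pnmal2, Pdgfrb, Selenbp1, Hdx and Pramel7 ended (adjusted p from 0.05 to 0.07).

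The comparison of TKO_96h with TKO_40h asks what the longest priming changes within TKO. Genes of hypoxia and glycolysis were far lower in TKO_96h. The glucose transporter genes Slc2a1 (chromosome 4, 119108711 to 119137983) and Slc2a3 were at 148 ± 10.2 against 959 ± 69.4 CPM and at 489 ± 41.2 against 2050 ± 41.2 CPM (log2 fold changes -2.7 ± 0.12 and -2.07 ± 0.1, adjusted p = 4.8e-12 and 1.3e-11). The mitophagy gene Bnip3 was at 11.7 ± 3.01 against 184 ± 27.5 CPM (-3.98 ± 0.16, adjusted p = 2.8e-12) and the collagen hydroxylase gene P4ha1 at 13.7 ± 0.449 against 143 ± 6.23 CPM (-3.38 ± 0.12, adjusted p = 2.4e-13). Among naive and formative pluripotency genes, Jam2 was at 97.5 ± 8.3 against 20.7 ± 2.74 CPM (2.23 ± 0.16, adjusted p = 6.8e-09) and the WNT effector Lef1 at 15.6 ± 4.89 against 121 ± 14.5 CPM (-2.95 ± 0.18, adjusted p = 7.1e-10).

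**Figure D2:**
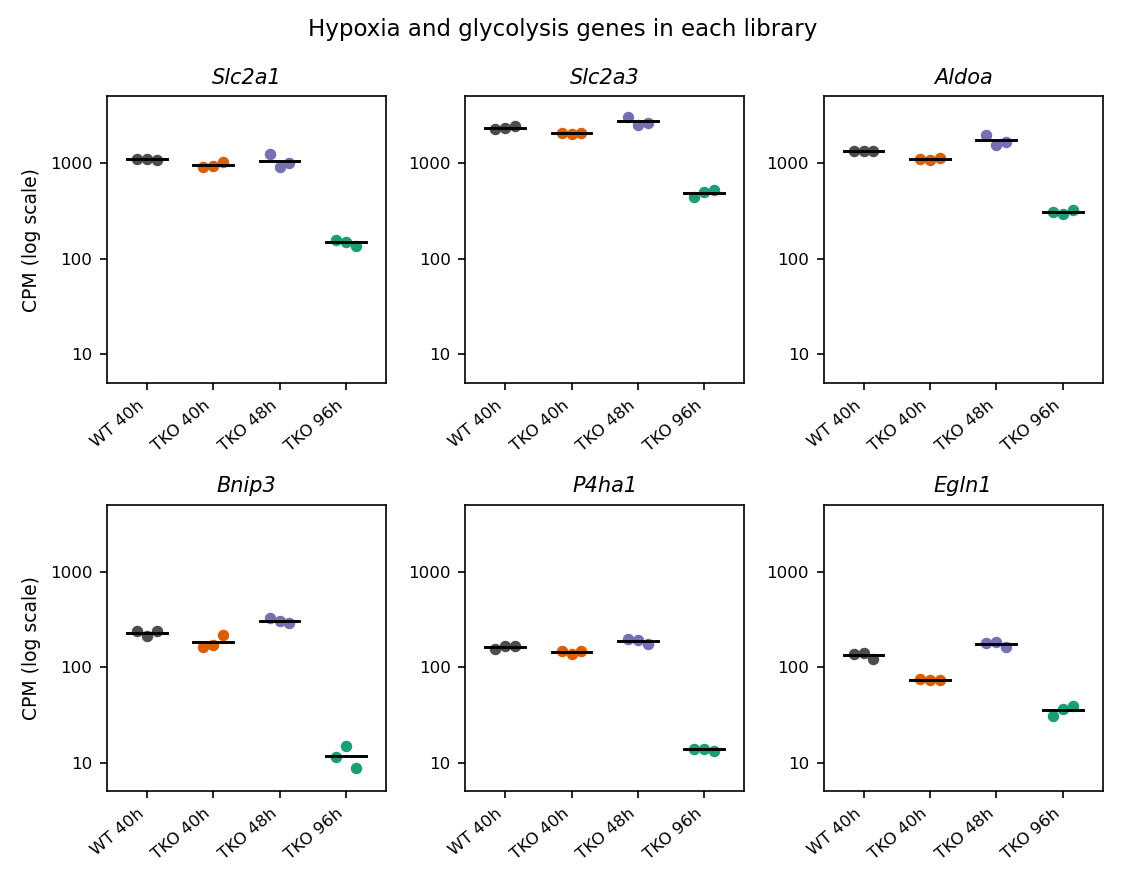
CPM on a log scale (vertical axis) of 6 hypoxia and glycolysis genes in each library (points), by group (horizontal axis), with the group mean as a line. In TKO_96h the means are 148 CPM for Slc2a1, 489 for Slc2a3, 307 for Aldoa, 11.7 for Bnip3, 13.7 for P4ha1 and 35.4 for Egln1, each below the means of the other 3 groups.

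Between TKO_96h and TKO_40h, 1965 of 16178 genes were called, 800 higher and 1165 lower in TKO_96h, and 662 of them at least 2-fold (155 higher, 507 lower). Within the limits of the naming rule, the largest increases were those of Krt42, Esrrg, Mras, Catip, Irak3, Slc11a1, Lrrc34 and Ms4a14, with log2 fold changes from 4.36 to 2.34. Among the largest decreases, the apolipoprotein gene Apoa4 and the GTPase gene Gem had no count in the 3 TKO_96h libraries and were at least 44.8-fold and 43.5-fold lower, taking 3 counts over the group as the floor. Thbs1 (thrombospondin), Ndufa4l2, Loxl2, Egln3, Fosb and Slc40a1 (ferroportin) were lower by log2 fold changes from -5.39 to -4.26, with Loxl2 at 2.91 ± 1.26 against 67.4 ± 4.87 CPM. The targeted genes Dnmt1 and Dnmt3a did not pass (0.26 ± 0.16 and -0.01 ± 0.17, adjusted p = 0.33 and 0.98) and Dnmt3b was lower by -0.57 ± 0.17 (adjusted p = 0.035).

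Of the 27 lists, 14 were called between TKO_96h and TKO_40h, and 7 of these also with an estimated correlation. Hypoxia and glycolysis genes had 0 of 23 higher and 19 lower (0 and 19 adjusted over the list alone), a median of -1.85 and adjusted p values of 3.8e-114 and 1e-04 with an estimated correlation. Immediate early and dissociation response genes had 1 of 19 higher and 12 lower (1 and 14 adjusted over the list alone), with the heat shock gene Hspa1b at 5.35 ± 1.25 against 34.5 ± 6.54 CPM. The immediate early list gave adjusted p = 1.1e-19, and adjusted p = 0.0052 with an estimated correlation. Formative and primed pluripotency genes had 1 of 22 higher and 11 lower (2 and 11 adjusted over the list alone), with Fgf5 at 1.94 ± 0.565 against 27.4 ± 3.25 CPM and the epiblast factor Otx2 at 40.5 ± 2.28 against 92.8 ± 4.26 CPM. The formative list gave adjusted p = 1.6e-12, and adjusted p = 0.033 with an estimated correlation. Methylation-sensitive germline genes had 2 of 37 higher and 14 lower (2 and 17 adjusted over the list alone), with the meiotic genes Tex11, Meioc and Smc1b lower by -1.73 ± 0.16, -1.46 ± 0.21 and -0.95 ± 0.14 and the ribosomal protein gene Rpl10l higher by 1.28 ± 0.17. The germline list gave adjusted p = 3.3e-07, and adjusted p = 0.015 with an estimated correlation. Paternally expressed imprinted genes had 0 of 21 higher and 7 lower (1 and 8 adjusted over the list alone), with Peg10 at 416 ± 49.8 against 3120 ± 69.3 CPM and its neighbour Sgce lower by -2.22 ± 0.22. The paternally expressed list gave adjusted p = 3.6e-05, and adjusted p = 0.011 with an estimated correlation.

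Trophoblast genes had 0 of 12 higher and 4 lower (0 and 5 adjusted over the list alone), with the keratin genes Krt8 and Krt18 at 2.29 ± 0.152 against 24.9 ± 2.66 CPM and 2.18 ± 0.812 against 19.5 ± 1 CPM. Peg10, counted above among the imprinted genes, is also 1 of these 4 lower genes (-2.91 ± 0.13, adjusted p = 6.2e-12). The trophoblast list gave adjusted p = 2.5e-09, and adjusted p = 0.011 with an estimated correlation. Endoderm genes had 0 of 19 higher and 6 lower (1 and 11 adjusted over the list alone), with Apob at 4.79 ± 2.84 against 33.8 ± 13.3 CPM, the laminin gene Lamb1 lower by -1.07 ± 0.18, and Afp and Apoa1, with no count in TKO_96h, at least 21.7-fold and 18-fold lower. The endoderm list gave adjusted p = 1.1e-05, and adjusted p = 0.039 with an estimated correlation. Their median of -1.18 is the same with these genes at their bound. Surface ectoderm genes had 0 of 15 higher and 5 lower (0 and 5 adjusted over the list alone), led by the epithelial factor Grhl2 at -1.42 ± 0.17. The surface ectoderm list gave adjusted p = 0.0073, and adjusted p = 0.081 with an estimated correlation. The 2-cell-like genes had 0 of 15 higher and 4 lower (0 and 6 adjusted over the list alone), and the summed Zscan4 copies were at 37.6 ± 30.3 CPM. The 2-cell-like list gave adjusted p = 1.8e-05, and adjusted p = 0.081 with an estimated correlation.

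Naive pluripotency genes had 9 of 20 higher and 2 lower (10 and 3 adjusted over the list alone), with the threonine dehydrogenase gene Tdh and Tbx3 higher by 1.71 ± 0.14 and 1.23 ± 0.14 and Klf2 lower by -0.79 ± 0.12. The naive list gave adjusted p = 4.1e-06, and adjusted p = 0.086 with an estimated correlation. Mitochondrially encoded mRNAs had 8 of 13 higher and 0 lower (8 and 0 adjusted over the list alone), with the cytochrome b mRNA mt-Cytb at 1990 ± 335 against 1350 ± 120 CPM; they took 1.87% of the counts in TKO_96h replicate 1, which stood apart, and 1.59 and 1.43% in replicates 2 and 3. The mitochondrial list gave adjusted p = 1.5e-05, and adjusted p = 0.16 with an estimated correlation. Integrated stress response genes had 0 of 22 higher and 6 lower (0 and 9 adjusted over the list alone), led by Stc2 and Ddit4, both also known to respond to hypoxia, at -3.83 ± 0.25 and -2.11 ± 0.18. The stress response list gave adjusted p = 4.1e-06, and adjusted p = 0.073 with an estimated correlation. Cholesterol biosynthesis genes had 0 of 20 higher and 8 lower (0 and 10 adjusted over the list alone). The cholesterol list gave adjusted p = 1.8e-05, and adjusted p = 0.14 with an estimated correlation. WNT targets had 0 of 12 higher and 3 lower (0 and 4 adjusted over the list alone), led by Lef1. The WNT list gave adjusted p = 0.012, and adjusted p = 0.082 with an estimated correlation.

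PGC genes went both ways in TKO_96h and were not called as a list (5 of 20 higher and 5 lower, 8 and 5 adjusted over the list alone; adjusted p = 0.34), with Dppa3 at 18.5 ± 2.12 against 51.5 ± 5.44 CPM, Ifitm3 higher by 1.46 ± 0.23 and the pluripotency factor Pou5f1 higher by 0.6 ± 0.12. Singled out after their values were seen, Prdm1 and Tfap2c, transcription factors that specify germ cells, were lower by -1.01 ± 0.23 and -0.79 ± 0.17 (adjusted p = 0.0067 and 0.0043). Cell cycle genes also went both ways (7 of 26 higher and 8 lower, 9 and 9 adjusted over the list alone; adjusted p = 0.25), with Mki67, Bub1 and Top2a lower by -0.92 ± 0.11, -0.78 ± 0.1 and -0.72 ± 0.1 and Rrm2 higher by 0.71 ± 0.1. The DNA methylation machinery had 2 of 18 higher and 2 lower (adjusted p = 0.44), with Dnmt3l lower by -1.43 ± 0.12. Neural genes had 4 of 21 higher and 2 lower (adjusted p = 0.087), mesoderm genes 1 of 20 higher and 2 lower (0.58), the other imprinted genes 2 of 16 higher and 3 lower (0.055), p53 targets 3 of 23 higher and 0 lower (0.055), interferon-stimulated genes 1 of 24 higher and 2 lower (0.38) and BMP targets 2 of 13 higher and 1 lower (0.087). The X-linked Rhox and Xlr (adjusted p = 0.22), endothelium and blood (0.58), Hox (0.13) and cytosolic ribosomal protein genes (0.47) were not called either.

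**Figure D3:**
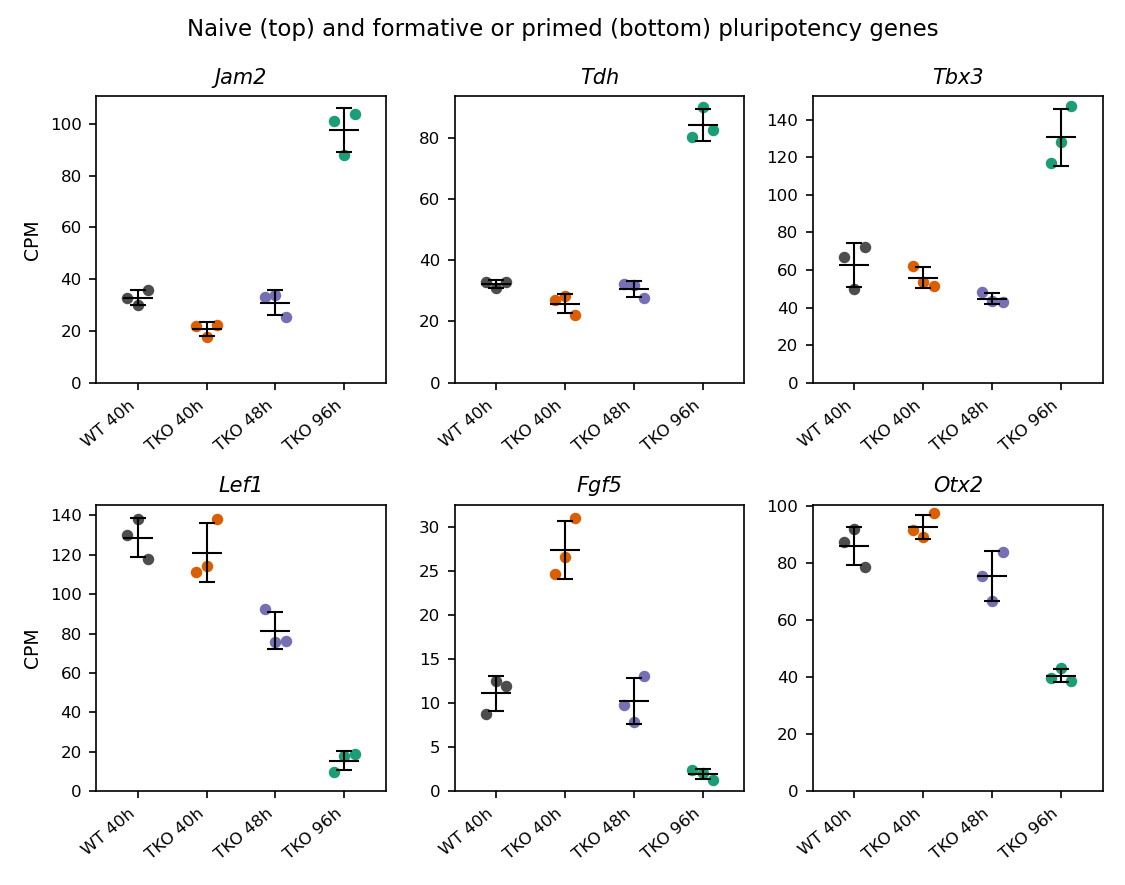
CPM (vertical axis, linear from 0) of the naive pluripotency genes Jam2, Tdh and Tbx3 and the formative or primed genes Lef1, Fgf5 and Otx2 in each library (points), by group (horizontal axis), with the mean and SD of 3 replicates as bars. The naive genes are highest in TKO_96h, with means of 97.5, 84.2 and 130 CPM, and the formative genes lowest there, with means of 15.6, 1.94 and 40.5 CPM.

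Without TKO_40h replicate 3 the number of genes called between TKO_96h and TKO_40h fell to 1210. The call of Dnmt3b ended without TKO_40h replicate 2 or 3 or TKO_96h replicate 1 or 2 (adjusted p of at most 0.17), that of Ms4a14 without TKO_40h replicate 1 or TKO_96h replicate 3 (0.073 for each), and that of Catip without any 1 library but TKO_40h replicate 2 (at most 0.14). With the length offset 830 genes were called; the calls of Dnmt3b, Catip, Slc11a1, Ms4a14 and Tfap2c ended (adjusted p = 0.071, 0.1, 0.092, 0.057 and 0.079). Of 120 called genes examined in this way 99 kept their call and 21 did not.

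Between TKO_96h and TKO_48h, which differ in their labels by the priming time, 3157 genes were called, 1427 higher and 1730 lower in TKO_96h, 1094 of them at least 2-fold. Hypoxia and glycolysis genes had 0 of 23 higher and 22 lower (0 and 22 adjusted over the list alone), a median of -2.58 and adjusted p values of 9.4e-144 and 3.5e-05 with an estimated correlation. Slc2a1 was lower by -2.85 ± 0.12 and Bnip3 by -4.71 ± 0.16. The other 13 of 14 lists called did not pass with an estimated correlation. Mitochondrially encoded mRNAs had 11 of 13 higher (11 adjusted over the list alone). The mitochondrial list gave adjusted p = 3.3e-09, and adjusted p = 0.14 with an estimated correlation. Cholesterol biosynthesis genes had 12 of 20 lower (12 adjusted over the list alone). The cholesterol list gave adjusted p = 2.2e-09, and adjusted p = 0.13 with an estimated correlation. Trophoblast genes had 1 of 12 higher and 4 lower (1 and 4 adjusted over the list alone). The trophoblast list gave adjusted p = 2.3e-05, and adjusted p = 0.097 with an estimated correlation. Prdm1 and Tfap2c, singled out as above, were lower by -1.73 ± 0.23 and -1.28 ± 0.17 (adjusted p = 2.9e-05 and 2.6e-05). Dnmt1, Dnmt3a and Dnmt3b were higher by 0.73 ± 0.16, 0.86 ± 0.17 and 0.81 ± 0.18 (adjusted p = 0.0032, 0.0016 and 0.0038), a call that ended for Dnmt3a with the length offset (0.48, adjusted p = 0.24), under which 1638 genes were called.

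TKO_48h and TKO_96h differ from WT_40h in genotype and priming time at once, and the 2 cannot be separated here. Against WT_40h, 916 genes were called in TKO_48h (460 higher, 456 lower, 247 at least 2-fold) and 3099 in TKO_96h (1473 higher, 1626 lower, 992 at least 2-fold). The DNA methylation machinery holds the 3 genes targeted in TKO, and without them, a test chosen after the values were seen, it was not called in TKO_48h (1 of 15 higher and 2 lower, 2 and 4 adjusted over the list alone; adjusted p = 0.8). Of the 27 lists, 13 were called in TKO_48h against WT_40h, and 1, the full methylation list, also with an estimated correlation. Called lower as well were the germline (0 of 37 higher and 7 lower), formative (2 of 22 and 4), mitochondrial (0 of 13 and 5) and immediate early lists (2 of 19 and 6). Their adjusted p values were 0.015, 1e-04, 1.8e-06 and 1e-04 by camera with the preset correlation. Dnmt3b, targeted in TKO and at -3.33 ± 0.18 in TKO_48h against WT_40h, also belongs to the formative list. That list was not tested without it. PGC genes were higher in TKO_48h (5 of 20 higher and 0 lower, 8 and 0 adjusted over the list alone). The PGC list gave adjusted p = 1e-04, and adjusted p = 0.075 with an estimated correlation. Lists of other cell types were called higher beside it: mesoderm with 3 of 20 higher and 0 lower (5 and 1 adjusted over the list alone), trophoblast with 3 of 12 and 0 (3 and 0), endothelium and blood with 3 of 14 and 0 (3 and 0), and surface ectoderm with 1 of 15 and 0 (1 and 0). In that order they gave adjusted p = 0.0014, 0.0031, 0.00049 and 0.022, and with an estimated correlation adjusted p = 0.08, 0.11, 0.11 and 0.16. Hypoxia and glycolysis genes had 5 of 23 higher and 0 lower in TKO_48h against WT_40h (13 and 0 adjusted over the list alone), a median of 0.39 and adjusted p values of 1.9e-07 and 0.11 with an estimated correlation. In the same comparison Dppa3, Grb10 and Cdkn1c were higher by 1.5 ± 0.2, 1.71 ± 0.18 and 1.94 ± 0.27. In TKO_96h, hypoxia and glycolysis genes had 0 of 23 higher and 21 lower (0 and 22 adjusted over the list alone), a median of -2.3 and adjusted p values of 5.1e-117 and 6.3e-05 with an estimated correlation. Naive pluripotency genes had 10 of 20 higher and 2 lower (12 and 2 adjusted over the list alone). The naive list gave adjusted p = 1.8e-06, and adjusted p = 0.11 with an estimated correlation. Formative genes had 0 of 22 higher and 12 lower (0 and 15 adjusted over the list alone), with the targeted gene Dnmt3b among those lower. The formative list gave adjusted p = 1.1e-12, and adjusted p = 0.058 with an estimated correlation. Peg10 was higher than in WT_40h by 0.55 ± 0.12 in TKO_48h (adjusted p = 0.011, and 0.064 without WT_40h replicate 1) and lower by -1.57 ± 0.12 in TKO_96h (adjusted p = 3.1e-08). The count for TKO_48h fell to 432, 396 and 409 without WT_40h replicates 1, 2 and 3, to 441 and 425 without TKO_48h replicates 1 and 3, and was 1540 without TKO_48h replicate 2. It was 586 in a fit on the 6 libraries alone and 238 with the length offset, which gave 1468 for TKO_96h.

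**Figure D4:**
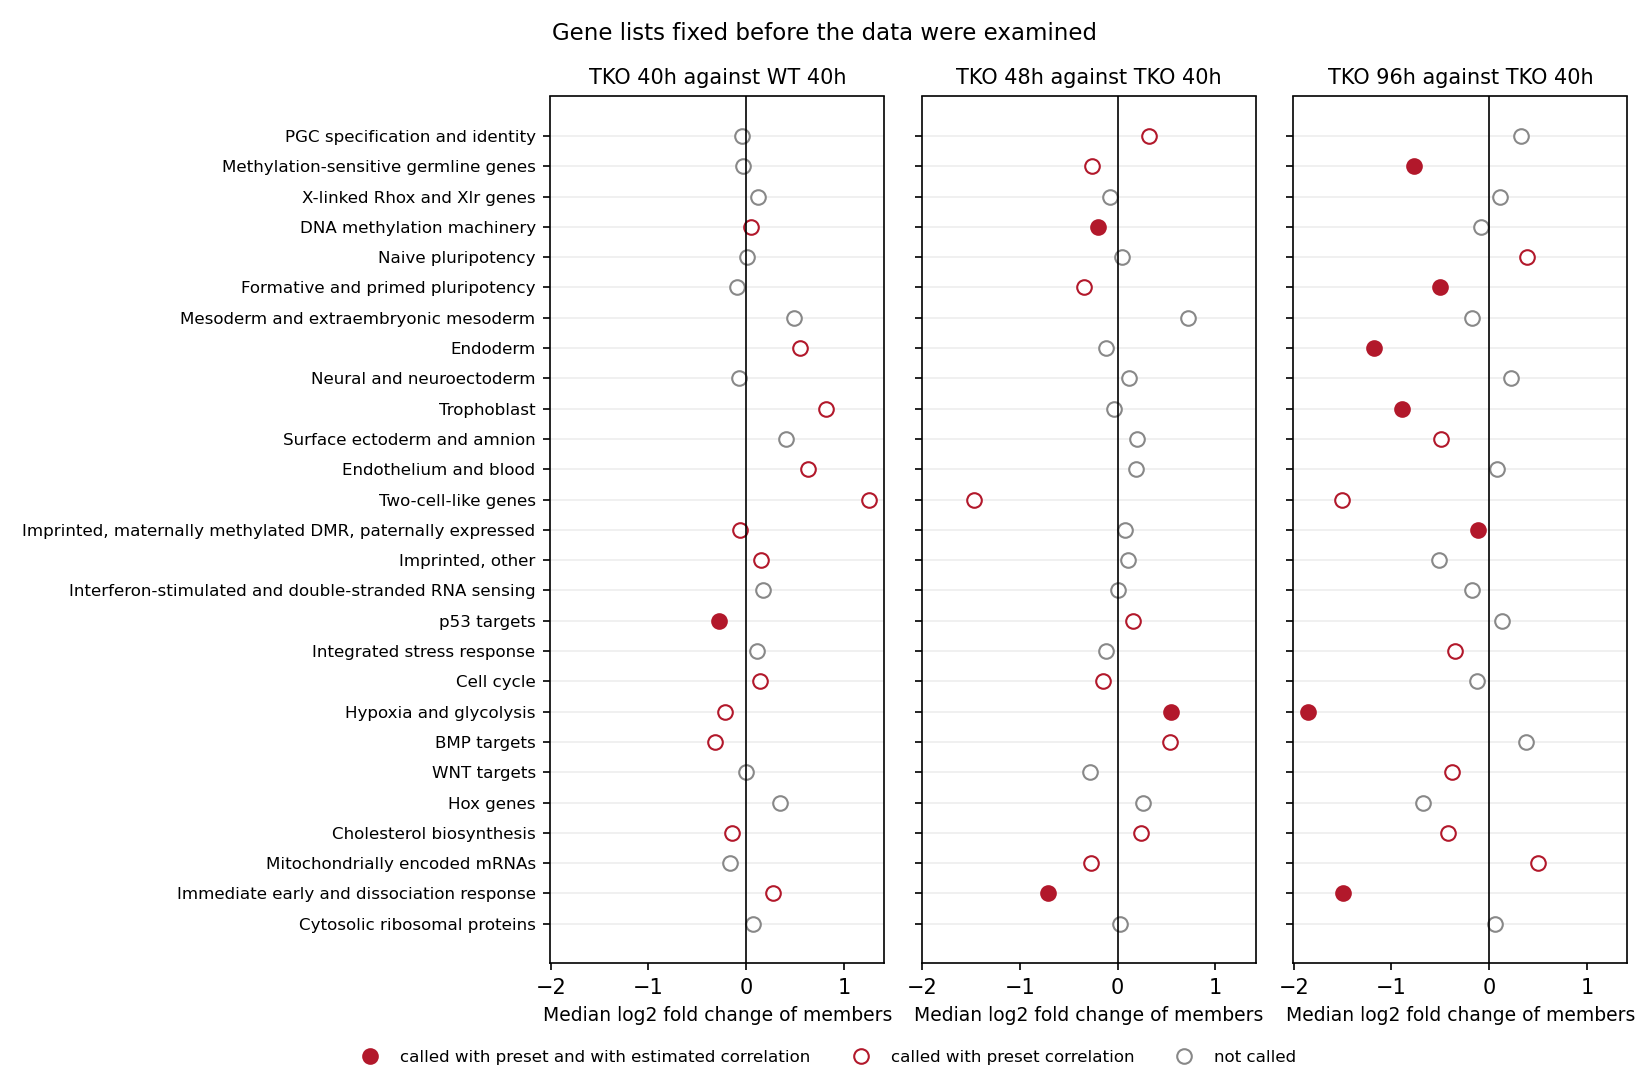
Median log2 fold change over the tested members of each of the 27 gene lists (horizontal axis) in the 3 main comparisons (panels). Filled red points are called with a preset and with an estimated correlation (1, 3 and 7 lists), open red points with the preset correlation alone, and grey points are not called; the median for hypoxia and glycolysis is -0.22, 0.55 and -1.85.

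Across the 3 priming times of TKO, 3440 of 16178 genes differed between at least 1 pair of times (F-test on 2 degrees of freedom), and 1618 with the length offset. TKO_40h takes part in each of the 3 main comparisons, so a high or low value in its 3 libraries moves the comparison with WT_40h and those with TKO_48h and TKO_96h in opposite directions. The p53, BMP, cholesterol, cell cycle and 2-cell-like lists were called in opposite directions in TKO_40h against WT_40h and TKO_48h against TKO_40h. In TKO_48h against WT_40h none of them was called (camera with the preset correlation, adjusted p = 0.12, 0.53, 0.26, 0.84 and 0.63). The hypoxia and immediate early lists, opposite in the same way, were called there. The p-values rest on the spread between cultures of the same group, estimated over all 4 groups together. The labels do not say whether the groups were grown, harvested and sequenced side by side.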

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

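The fit on protein-coding genes alone, without Lars2, Ccnb1ip1 and Gm20594, the DNA methylation machinery without Dnmt1, Dnmt3a and Dnmt3b and the gene families without TKO_96h replicate 1 were chosen after seeing the data; all other alternatives were fixed beforehand. With RLE size factors, DESeq2, the robust fit, the replicate block and protein-coding genes alone, the counts of called genes stayed within 1.5 times the reported ones in all 6 comparisons and in the test over priming times. They ran from 492 to 724 for TKO_40h against WT_40h, 882 to 1111 for TKO_48h against TKO_40h and 1952 to 2194 for TKO_96h against TKO_40h.

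The offset for effective transcript length called 77 genes between TKO_40h and WT_40h, 203 between TKO_48h and TKO_40h, 830 between TKO_96h and TKO_40h, 1638 between TKO_96h and TKO_48h, 238 between TKO_48h and WT_40h, 1468 between TKO_96h and WT_40h, and 1618 over the priming times. With it the biological coefficient of variation was 0.333, against 0.241; why the spread grew was not tested. Among named genes called in the reported fit, the offset turned 1, the imprinted regulator Plagl1, from 1.2 (adjusted p = 0.019) to -0.1 (adjusted p = 0.98) in TKO_40h against WT_40h. The cause was not tested. Without a filter on low counts 787 genes were called between TKO_40h and WT_40h. A fit on only the groups compared called 1279 genes for TKO_40h against WT_40h and 586 for TKO_48h against WT_40h, estimating the spread from 6 libraries.

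Of the 13, 12 and 14 lists called in the 3 main comparisons, an estimated correlation left 1, 3 and 7, and fry called 11, 13 and 20. With 1 library left out at a time, which leaves 2 in a group, 181 to 217 genes were called for TKO_40h against WT_40h, 324 to 1107 for TKO_48h against TKO_40h, 1210 to 1676 for TKO_96h against TKO_40h, 2344 to 2991 for TKO_96h against TKO_48h, 396 to 1540 for TKO_48h against WT_40h, 2084 to 2645 for TKO_96h against WT_40h and 2709 to 3556 over the priming times. Lists called then numbered 10 to 16, 11 to 14 and 14 to 16.

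Over all alternatives, 4133 values of named genes were counted as unchanged. These kept their direction and their side of the threshold, or belonged to genes not called in the reported fit whose direction changed. Calls were lost 554 times and gained 15 times, and a called gene reversed 1 time. Of the losses 117 came with the length offset. The replicate block ended the calls of Ccdc113, Tmem132d and Hoxb13 in TKO_40h against WT_40h (adjusted p = 0.055, 0.054 and 0.057) and of Selenbp1 and Pramel7 in TKO_48h against TKO_40h (0.051 and 0.059). At this depth 64 to 69% of simulated 2-fold changes were recovered, so that a gene that was not called is not shown to be unchanged.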

Other observations

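The gene families, the split counts and the tests of other cell types, shared sequence and chaperones were chosen only after the result was seen. The tests on GC content and length and on ERK feedback genes were set before it. In TKO_96h against TKO_40h, collagens, claudins, keratins and kinesins were called lower as families with a preset correlation, none with an estimated one, and laminins were not called (1 of 10 higher and 2 lower, adjusted p = 0.15). Col4a2 and Col4a1, the chains of basement membrane collagen, were lower by -1.28 ± 0.15 and -1.21 ± 0.15 (log2 fold change ± SE, adjusted p = 6.8e-06 and 1.8e-05). Collagens as a family had 1 of 33 higher and 6 lower (adjusted p = 0.0094, adjusted p = 0.33 with an estimated correlation). The tight junction genes Cldn6, Cldn7 and Cldn4 were lower by -3.12 ± 0.37, -3.54 ± 0.45 and -1.14 ± 0.23 (adjusted p = 1e-05, 2.6e-05 and 0.0023). Claudins had 0 of 9 higher and 3 lower (adjusted p = 0.0018, adjusted p = 0.17 with an estimated correlation). Krt19, a keratin of simple epithelia, was lower by -3.08 ± 0.63 (adjusted p = 0.0026). Keratins had 1 of 11 higher and 3 lower, with a median of 0.13, a mean of -0.29 and a test that pointed down (adjusted p = 0.031, adjusted p = 0.26 with an estimated correlation). Kif21a, a kinesin motor gene, was at 17.6 ± 5.98 against 69.7 ± 5.19 CPM (adjusted p = 6.2e-07). Kinesins had 0 of 35 higher and 8 lower (adjusted p = 4e-04, adjusted p = 0.21 with an estimated correlation), and 5 of 37 lower without TKO_96h replicate 1 (adjusted p = 0.006, adjusted p = 0.081 with an estimated correlation).

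Other families were called higher in TKO_96h than in TKO_40h, again none with an estimated correlation. Mitochondrial ribosomal protein genes had 18 of 75 higher and 0 lower (adjusted p = 1.4e-09, adjusted p = 0.33 with an estimated correlation). Mrpl11 was at 48.9 ± 9.9 against 24.6 ± 4.28 CPM. Subunits of respiratory complex I had 7 of 36 higher and 0 lower (adjusted p = 6.6e-06, adjusted p = 0.54 with an estimated correlation). Ndufa5 was at 84 ± 29.6 against 40.1 ± 1.49 CPM. Proteasome subunits had 7 of 48 higher and 0 lower (adjusted p = 1e-04, adjusted p = 0.54 with an estimated correlation). Psmc5 and Psmc3 were higher by 0.68 ± 0.13 and 0.65 ± 0.13. Replication-dependent histones, whose copies share much of their sequence so that counts per gene are uncertain, had 16 of 66 higher and 0 lower (adjusted p = 6.6e-06, adjusted p = 0.61 with an estimated correlation). The histone gene of smallest adjusted p, Hist1h2af, was at 408 ± 162 against 227 ± 10.4 CPM (adjusted p = 0.011). Its call ended without TKO_40h replicate 3 (adjusted p = 0.053), without TKO_96h replicate 1 (adjusted p = 0.11) and with a robust fit (adjusted p = 0.1). TKO_96h replicate 1 stood apart in its group, and without it histones had 0 of 66 higher and 1 lower and were not called (adjusted p = 0.23). Mitochondrial ribosomal protein, complex I and proteasome genes then had 3 higher each, of 75, 36 and 48 (adjusted p = 9.3e-06, 0.016 and 0.021, and with an estimated correlation adjusted p = 0.44, 0.84 and 0.84). Of 26 families tested, 14 were called between TKO_96h and TKO_40h and none with an estimated correlation, where the lowest adjusted p was 0.17.

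For each comparison of 3 libraries with 3, the 10 splits are too few for a share under 0.05, and 1 of the 10, the real one, called as many genes. The real counts were 501, 888, 1965, 3157, 916 and 3099, and the highest counts of the other splits were 1, 0, 0, 1, 0 and 0 (TKO_40h against WT_40h, TKO_48h and TKO_96h against TKO_40h, TKO_96h against TKO_48h, TKO_48h and TKO_96h against WT_40h). Over the priming times of TKO, 1 of 60 splits drawn, the real one, gave as many as 3440 genes, and the highest other gave 1551. That share is under 0.05, which argues against a chance arrangement of the libraries. The splits cannot speak to handling shared by the libraries of a group, which would give the same outcome.

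The fall of hypoxia and glycolysis genes in TKO_96h against TKO_40h had a median of -1.85 over 23 members (SD 1.15). After trends on GC content and length were taken out, which shifted all genes by a median of 0.088, the median was -2 (SD 1.17) and 17 of 23 members lay below -1, against 18 before, which argues against such a trend as the whole cause. Fewer cells of another type cannot be told apart from a change within cells: among the 6 lists of other cell types the lowest median was that of endoderm, -1.18, within the SD of its members (1.42) of the fall, and its members had a median level of 6.28 CPM in TKO_40h; this test replaced one on PGC genes after the result of that one was seen. The labels name 5 characteristics, 0 of them a batch, date, run or lane, so separate handling of the cultures of each priming time was not tested and stays open. A response of the cells to longer priming may also account for it and was not tested.

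Tmem72 was higher in TKO_40h than in WT_40h by 1.42 ± 0.22, a call that ended with a robust fit (adjusted p = 0.051). After the trends on GC content and length it was 1.47, which argues against a general trend on these over all genes as the cause. A bias particular to the sequence of Tmem72 was not tested. Of 51 genes that share at least 100 words of 31 bases with its longest transcript 18 were tested, and all 18 had positive log2 fold changes with a median of 0.52 (SD 0.62); the 3 called, named after their values were seen, were AC124237.1 at 1.54 ± 0.23, Gm47924 at 1.34 ± 0.25, whose call ended with the robust fit (adjusted p = 0.092), and Slc25a20 at 1.13 ± 0.16. In TKO_48h and TKO_96h against TKO_40h the medians of these genes were -0.74 and -0.81. Of the tested genes, Gm47924, Gm48113 and AC124237.1 shared the most words, 976, 843 and 795. Gm47924 and AC124237.1 changed much like Tmem72 there too. In TKO_48h they were at -2.28 and -2.3, against -2.26 for Tmem72, and in TKO_96h at -2.1 and -2.22, against -2.2. Gm48113 was at 2.44 ± 1.07 in TKO_40h against WT_40h and was not called. Reads of a repeated sequence, credited alike to Tmem72 and to the genes that share its words, may account for part or all of its level. They cannot be told apart from a change of Tmem72 itself, because the median of the 18 genes, 0.52, lies between the bounds set for the test and the spread is wide.

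Fos, Fosb, Egr1 and Junb, induced within minutes by growth factors or stress, were lower in TKO_48h than in TKO_40h by -2.14 ± 0.27, -3.7 ± 0.26, -2.71 ± 0.16 and -1.29 ± 0.19. Lower output of the ERK pathway may be behind this: 11 ERK feedback genes had a median of -0.16 (SD 0.33, SE 0.1), 1 was called higher and 2 lower, and camera put them lower than other genes before any adjustment. The median lies on the side of the bound, set beforehand, that speaks against this explanation, but by less than its SE, and the demand for a margin was added after the value was seen, so it cannot be told apart. Less stress from handling and dissociation cannot be told apart either: the chaperone genes had a median of -0.49 with 3 of 4 lower, Hspa1b and Hsph1 called at -0.76 ± 0.2 and -0.71 ± 0.12, and Hspa1a not called at 0.46 ± 0.35. Priming time, the difference the design names, stays open and was not tested separately.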
